A study of Mus musculus with 10 samples.

How the data were processed

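Bulk RNA-seq of tumours from mice bearing B16F10, a mouse melanoma cell line, was analysed. Per the series' design text, 5 mice received saline and 5 received the M44 vaccine, which is 50 µg of a peptide named M44 formulated with 20 µg of CpG, an oligonucleotide adjuvant. Both were given under the skin on days 2 and 8, and the tumours were taken on day 10. The design text calls the vaccine MHC class II-restricted. No group received CpG alone, so an effect of the peptide and one of CpG cannot be told apart in these data. Per the labels' protocols, tumour pieces were snap-frozen, RNA was isolated with a Qiagen RNeasy Plus Mini kit, and libraries were made with an Illumina TruSeq RNA kit. Whether that kit kept the strand is not given in the sources used here, so reads of a gene and of an antisense partner cannot be separated.

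Per the submitters' processing notes, STAR 2.7.8, featureCounts 1.6.4 and the GRCm39 mouse genome were used. The notes give neither their order nor the gene annotation or counting settings. The deposited counts are whole numbers of reads per gene symbol, not normalized, for 55258 symbols in 10 libraries, 1 per tumour. The deposited TPM values cover the same symbols and libraries. Each TPM column sums to between 998455 and 998826. For 11145 of 11148 genes with at least 50 reads in every library, the ratio of counts to TPM gave 1 length per gene in every column within a tolerance of 1%, so the TPM values hold the same reads as the counts. No symbol was duplicated, and no line was blank or a total. Columns were tied to tumours by the number and treatment word in their names. Library totals ran from 26248031 to 46156595 counts. A gene with no read in a library could be present at up to 3 counts of the total, which is 0.0650 to 0.114 CPM, the count scaled to library size. Such floors and the intervals given for shares cover counting error only. In a comparison of all 45 library pairs, the chi-square per degree of freedom over genes with 20 or more reads was at least 6.70, so no library was a repeat of another and each tumour counts once.

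The comparison of M44 vaccine with saline tumours was made on the counts with edgeR 4.0.16's quasi-likelihood F test (robust glmQLFit, glmQLFTest) after TMM scaling, in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 15255 genes. Genes with a Benjamini-Hochberg adjusted p below 0.05 are said to have risen or fallen, and the adjusted p of a gene is edgeR's unless another tool is named. Log2 fold changes are M44 vaccine minus saline. Their standard errors (SE) are the size of the fold change divided by the square root of the F statistic. CPM values use TMM-scaled library sizes. Group values are means ± SD with n = 5 tumours, each from another mouse.

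A set of 42 gene lists, 22 of cell type markers and 20 of pathways, was fixed before the data were examined, as were the tests, the groups, most alternatives and the rule for named genes. Of the 572 list entries, 568 were found among the symbols and 458 passed the filter. Lists with at least 3 tested members, 38 in all, entered camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Camera asks whether a list's genes moved more than all other genes. Counts of members are given over all genes tested and adjusted over the list alone. Camera was repeated with an estimated correlation, and fry was run on the same values. A mean per list and tumour was taken over log2 CPM values, each gene centred on its mean over the 10 tumours, and compared with a two-sided exact permutation test over all splits, whose smallest possible p is 0.00794. Its adjusted values are Benjamini-Hochberg over the 38 lists.

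The rule for named genes took, in each direction, the 12 genes with the largest fold change among those past the test with a mean log2 CPM of at least 0, leaving out symbols of predicted genes (Gm with a number, Rik, or pseudogene endings). It took up to 4 past-the-test members of each list with the smallest adjusted p, or the 2 members with the smallest unadjusted p where none passed. It always took a fixed set of genes, among them Cd4, Cd8a, Foxp3, Ifng, Gzmb, Pdcd1, Cd274, H2-Ab1, H2-K1, Tyrp1, S100a8, Arg1, Nos2 and Ints11. Not every gene that the rule took is given in the text. Lists that neither passed camera nor held a member past the test may be given as counts.

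The same edgeR code was tested on simulated data for this comparison. Both groups were drawn from the saline tumours' mean shares and the real library sizes. Outside the lists 200 genes were changed, and the T cell, macrophage and proliferation lists were changed by 4-fold. The recovery therefore holds for saline expression levels, and no simulated tumour was made to stand apart from its group. On the 14834 genes that passed the filter, the edgeR code recovered 18 of 67 genes outside the lists changed by 1.5-fold. It recovered 44 of 67 changed by 2-fold and 54 of 66 changed by 4-fold. It made 155 calls, members of the changed lists included, and 9 of these were unchanged genes. Camera recovered 3 of 3 changed lists and called 1 of 31 others, complement, which shares C1qa, C1qb and C1qc with a changed list. The simulated genes were drawn independently, so this cannot show how camera performs where a list's genes move together. For the T cell list of the real tumours, the estimated correlation was 0.76.

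Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma voom with sample quality weights, no filter beyond 1 read, a filter of 1 CPM in 5 libraries, the replicate number as a block, each library left out in turn, limma on log2(TPM + 1) and log2(TPM + 0.1) for genes with a TPM of at least 1 in 5 libraries or unfiltered, and a minimum absolute log2 fold change of 1. The sample quality weights were 0.121 and 0.126 for M44 vaccine tumours 1 and 2 and 0.662 to 2.95 for the others. The weighted fit thus counts those 2 tumours least and is not a separate check on a fit without them. Leaving out M44 vaccine tumours 1 and 2 together, and removing trends with gene length and GC content, were chosen after seeing the data. Length and GC content came from GENCODE M21 transcripts of the older GRCm38 build by symbol, for 97.2% of the genes tested. No coordinates were used, because the build at hand differs from the submitters'. Reads that near-identical copies could share, as among alpha and beta globin genes, H2-Q and H2-T genes, Gbp, Tgtp and Klra families and immunoglobulin segments, make single-gene values of those families uncertain.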

Results

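RNA was sequenced from 10 B16F10 melanoma tumours, 5 from mice given saline and 5 from mice given the M44 vaccine, to ask how a vaccine described as MHC class II-restricted changes gene expression in the tumour. The saline libraries held 26248031 to 30903055 counts and the M44 vaccine libraries 28406795 to 46156595. Mitochondrially encoded genes took 3.79 ± 0.502% of counts in saline tumours and 6.26 ± 1.89% in M44 vaccine tumours (SD, n = 5; two-sided exact permutation p = 0.00794, the smallest this test can give). The shares were highest in M44 vaccine tumours 1 and 2, at 7.81% (95% exact binomial interval 7.80 to 7.82%) and 8.74% (8.73 to 8.75%). The first principal component of log2 CPM held 63.4% of the variance. On it, the saline tumours lay between -48.4 and -37.8. M44 vaccine tumours 1 and 2 lay at 99.5 and 95.4, tumours 3 and 4 at 17.2 and 18.6, and tumour 5 at -15.8.

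Tumours of vaccinated mice carried more transcripts of cytotoxic lymphocytes, of antigen presentation and of myeloid cells, and fewer transcripts of erythroid genes such as the globins. H2-Ab1, an MHC class II chain, stood at 8.56 ± 2.21 CPM in saline and 265 ± 183 CPM in M44 vaccine tumours (SD, n = 5), 31.0-fold higher. Gzmb, a granule protease of killer lymphocytes, was 41.8-fold higher, and Cd8a, a coreceptor of cytotoxic T cells, 44.9-fold. Mitf, the transcription factor that directs the melanocyte lineage, fell 2.26-fold, and Hbb-bs, an adult beta globin gene, 38.3-fold, a log2 fold change of -5.26 that became -3.53 without saline tumour 4. For Cd8a the log2 fold change was 5.49, and 6.17 without saline tumour 1. In all, 2400 of 15255 genes rose, with a median log2 fold change of 0.76, and 1610 fell, with a median of -0.54. Of these, 1007 rose and 195 fell by at least 1 on the log2 scale. The 2 groups did not overlap at 1716 genes higher and 1870 genes lower in M44 vaccine tumours, 23.5% of genes against 0.794% by chance. Of 38 gene lists, 21 were higher and 2 lower by camera. With a correlation estimated from the data camera called 0 higher and 0 lower, and 0 had an unadjusted p below 0.05. Fry called 21 higher and 1 lower, of which 19 and 1 were also called by camera with the preset correlation. Other splits of the 10 tumours gave up to 25 lists higher and 8 lower, so the number of lists called by camera does not set the treatment apart from chance. Those splits still held 3 or 4 of the 5 M44 vaccine tumours on 1 side, so they are not free of a difference between the groups. The exact permutation test on list means called 23 of 38 lists, 17 of them at the smallest p that it can give.

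The share of higher against lower genes was not the same in every fit. Limma on log2 CPM gave 2019 higher and 1825 lower genes. Limma on log2(TPM + 1), with another filter, gave 791 higher and 2958 lower, with a median log2 fold change of all genes at -0.26 against 0.01 with TMM. Changes of about that size therefore depend on the fit, and the log2(TPM + 1) fit changed the tool and the filter besides the scale. The median of the B cell list went from 1.24 to -0.19 on that scale, with 2 of 5 members left. That of hypoxia and glycolysis went from 0.35 to -0.01, of the p53 response from 0.47 to -0.21, and of the unfolded protein response from 0.09 to -0.19. That of immediate early and heat shock genes went from 0.20 to -0.12. All genes moved on that scale, and relative to their median none of these 5 lists was below 0: the values were 0.07, 0.24, 0.04, 0.06 and 0.13 in the order given. Leaving out 1 tumour moved the counts of genes higher or lower by over 1.5 times for 8 of the 10. The number higher was 1427, 1190, 1011, 1183 and 1113 without saline tumours 1 to 5, and 1464 without M44 vaccine tumour 2. The number lower was 783, 579, 382, 539 and 447 without saline tumours 1 to 5, and 969, 743 and 2555 without M44 vaccine tumours 1, 2 and 5. With M44 vaccine tumours 1 and 2 left out together, a choice made after seeing the data, 2271 genes were higher and 1841 lower. Of the 2400 genes that rose with all tumours 1808 were among them, as were 1281 of the 1610 that fell.

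Among genes past the test with a mean log2 CPM of at least 0, the 12 with the largest rise follow. Nkg7, a granule protein of cytotoxic cells, rose by a log2 fold change of 5.40 (SE 0.83, adjusted p = 0.00591), from 0.194 ± 0.107 to 8.38 ± 6.78 CPM. Gzmb rose by 5.39 (SE 0.79, adjusted p = 0.00520). The immunoproteasome subunit Psmb8 rose by 4.96 (SE 0.76), from 3.89 ± 2.82 to 121 ± 89.6 CPM. The class II genes H2-Ab1, H2-Eb1, H2-Aa and Cd74, the invariant chain, rose by 4.95, 4.91, 4.79 and 4.65 with SEs of 0.57 to 0.63. The macrophage gene Aif1 rose by 4.87, Slamf8 by 4.67, Slamf9 by 4.61, or by 3.94 without M44 vaccine tumour 1, and the monocyte marker Ly6c2 by 4.60. Each of these 11 genes was higher in 5 of 5 M44 vaccine tumours than in any saline tumour. The remaining gene, Serpinb2, an inhibitor of plasminogen activators, had a log2 fold change of 4.56 (SE 1.45, adjusted p = 0.0429). Only 3 M44 vaccine tumours lay above the saline range and 2 lay below it, and with sample quality weights its log2 fold change was -1.49. Its log2 fold change was 5.45 without saline tumour 2 and 3.65 without M44 vaccine tumour 2. Its call was lost without any 1 of 7 tumours, the 5 saline tumours and M44 vaccine tumours 1 and 2, with adjusted p between 0.0612 and 0.0955.

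Genes of T cells and of cytotoxic lymphocytes rose. All 15 of 15 measured members of the T cell list passed the test, 15 adjusted over the list alone, with a median log2 fold change of 3.50. Cd3e, Cd3d, Cd5 and Trac, which encode parts or partners of the T cell receptor, rose by 3.90, 5.54, 3.47 and 4.04 (SE 0.53 to 0.87). The list passed camera (adjusted p = 2.80e-09; adjusted p = 0.336 with an estimated correlation). Likewise 9 of 9 cytotoxic lymphocyte genes rose, 9 adjusted over the list alone, among them Prf1, the pore-forming protein perforin, by 4.69, and the chemokine gene Ccl5 by 3.53 (camera adjusted p = 6.16e-07; 0.336 as the adjusted p with an estimated correlation). Cd8a rose by 5.49 (SE 0.88, adjusted p = 0.00616), from 0.149 ± 0.161 to 6.87 ± 4.50 CPM, or by 6.17 without saline tumour 1, and was above the saline range in 5 of 5 M44 vaccine tumours. With tumours 1 and 2 of the vaccine group left out, 14 of 15 T cell genes and 9 of 9 cytotoxic genes rose.

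Genes of the CD4 helper and Th1 list rose as well. Cd4, the coreceptor of helper T cells, went from 0.467 ± 0.114 to 3.36 ± 2.11 CPM (log2 fold change 2.84, SE 0.51, adjusted p = 0.00757), above the saline range in 5 of 5 M44 vaccine tumours. In the CD4 helper and Th1 list 5 of 7 members passed the test, 5 adjusted over the list alone. Cxcr6, Stat4 and Tnf rose by 4.03, 2.54 and 3.77, and Tnf is also in the inflammatory macrophage list. The list passed camera (adjusted p = 0.000609; adjusted p = 0.336 with an estimated correlation). Its median was 2.54, but -0.08 on log2(TPM + 1), or 0.17 relative to the median of all genes, where 3 members passed the filter and the list did not pass camera (adjusted p = 0.242). Ifng, the gene of interferon gamma, had 1, 2, 1, 1 and 0 reads in saline tumours 1 to 5 and 15, 137, 26, 22 and 3 in M44 vaccine tumours 1 to 5, and it did not enter the test because too few tumours had enough. With no filter beyond 1 read its log2 fold change was 4.79 (edgeR adjusted p = 0.00993), and 4.92 by DESeq2 (adjusted p = 2.83e-05). Pdcd1, the PD-1 receptor gene, likewise had 3.93 (adjusted p = 0.0249) and 3.97 (adjusted p = 7.76e-05). An exact permutation test on CPM called neither (adjusted p = 0.0648 for Ifng and 0.0972 for Pdcd1). That test was adjusted over 49 genes below the filter and called 0 of them. Ifng had the smallest p that it can give, 0.00794, and lay above the saline range in 5 of 5 M44 vaccine tumours. Even that p became 0.0648 when adjusted, so the missing call does not speak against a rise of Ifng. The regulatory T cell marker Foxp3 stood at 0.276 ± 0.117 and 0.413 ± 0.105 CPM (adjusted p = 0.238). In the regulatory T cell list 2 of 6 genes rose, and 2 adjusted over the list alone. These were Il2ra, by 1.69, and Tnfrsf4, by 1.43, but the list did not pass camera (adjusted p = 0.0912). It did so without saline tumour 5 (adjusted p = 0.0432) or without M44 vaccine tumour 5 (adjusted p = 0.0451). With all tumours it passed camera after trends with gene length and GC content were removed (adjusted p = 0.0246), and it passed fry (adjusted p = 0.0436). With an estimated correlation it did not pass camera (adjusted p = 0.422). Both gene calls were lost without single tumours, saline 1, 2, 3 or 4 and M44 vaccine 1 or 2 for each and also M44 vaccine 4 for Il2ra (adjusted p up to 0.0787 and 0.0917).

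Transcripts of the natural killer cell list were scarce in saline tumours, and which cells made them was not tested. Klrk1, the receptor NKG2D, was the only list member with enough reads for the test and rose by 4.72 (SE 0.75, adjusted p = 0.00616), from 0.117 ± 0.0858 to 3.14 ± 2.45 CPM. The other 10 members, among them Ncr1 with 2 reads in all saline and 63 in all M44 vaccine tumours, Klrb1c with 5 and 102, and Xcl1 with 2 and 74, were below the filter; these 3 were picked after their values were seen. With no filter beyond 1 read, Ncr1, Klrb1c and Xcl1 had log2 fold changes of 4.41, 3.96 and 4.62 (edgeR adjusted p = 0.0217, 0.0131 and 0.00534). By an exact permutation test on CPM none of the 3 passed (adjusted p = 0.156, 0.0648 and 0.0648). Klrb1c and Xcl1 had the smallest p that this test can give before adjustment, so for them it cannot decide.

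**Figure D1:**
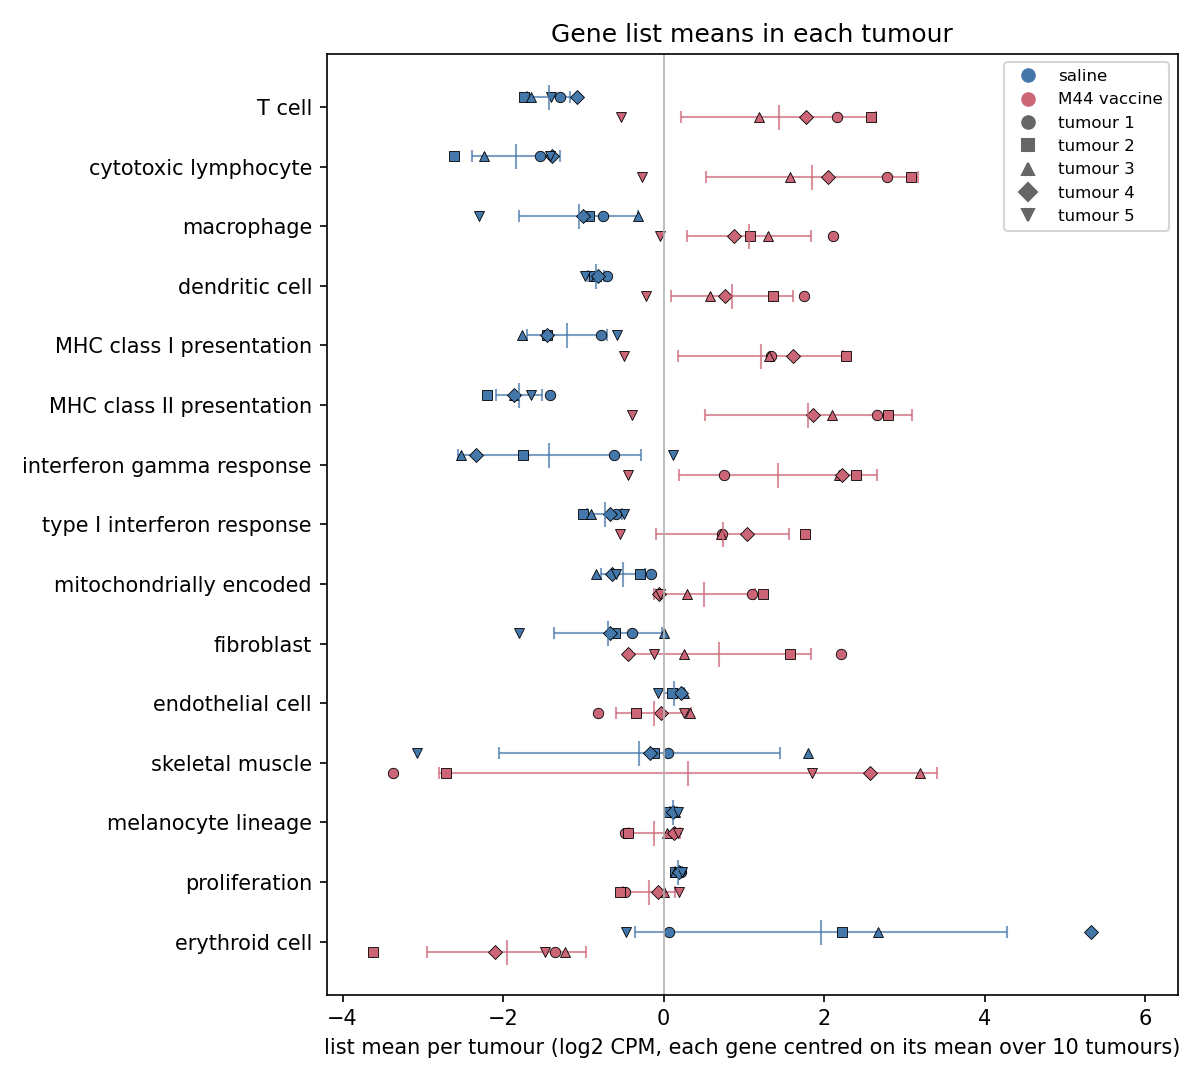
Mean log2 CPM of 15 gene lists in each tumour, every gene centred on its mean over the 10 tumours (blue, saline; red, M44 vaccine; shape, tumour number; bars, mean and SD, n = 5). The M44 vaccine tumours lie above all saline tumours for the T cell list, tumour 5 closest to them at -0.53, and below all of them for the erythroid list.

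Antigen presentation genes rose in both MHC classes. In class II presentation 9 of 10 members passed the test, 10 adjusted over the list alone, with a median log2 fold change of 4.03 (camera adjusted p = 1.39e-07; adjusted p = 0.336 with an estimated correlation). Cd74 went from 21.6 ± 6.44 to 539 ± 295 CPM and H2-Aa from 10.5 ± 3.72 to 292 ± 174 CPM. In class I presentation 16 of 17 members rose, 17 adjusted over the list alone, with a median of 2.50 (camera adjusted p = 2.80e-09; adjusted p = 0.336 with an estimated correlation). The heavy chain genes H2-K1, H2-D1 and H2-T22 rose by 2.55, 2.60 and 2.34, and the light chain gene B2m by 1.73, from 340.3 ± 102 to 1131 ± 395 CPM. H2-T22 belongs to a family of near-identical copies that may share reads, so its value is uncertain. Per tumour, the class II mean was 2.66, 2.79, 2.10, 1.86 and -0.40 in M44 vaccine tumours 1 to 5, against -1.80 ± 0.29 in saline tumours (SD, n = 5; exact permutation p = 0.00794, adjusted 0.0177). Of the class II genes 9 of 10, and of the class I genes 15 of 17, also rose without M44 vaccine tumours 1 and 2.

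Interferon-induced genes rose. Of the interferon gamma response list 23 of 24 members passed the test, 23 adjusted over the list alone, with a median log2 fold change of 2.86 (camera adjusted p = 2.12e-09; adjusted p = 0.336 with an estimated correlation). The guanylate-binding protein gene Gbp8 rose by 4.47, Serpina3g by 4.48 and the class II transactivator Ciita by 3.50, from 1.51 ± 0.801 to 17.1 ± 10.1 CPM. The list mean overlapped between the groups: it was -0.62 and 0.11 in saline tumours 1 and 5, -1.76, -2.52 and -2.34 in saline tumours 2 to 4, and -0.44 in M44 vaccine tumour 5 (exact permutation p = 0.0159, adjusted 0.0287). Without M44 vaccine tumours 1 and 2, 7 of 24 members rose, at a median of 2.90. In the type I interferon response 18 of 21 members rose, 19 adjusted over the list alone, with a median of 1.51 (camera adjusted p = 5.01e-07; adjusted p = 0.336 with an estimated correlation). The list mean of M44 vaccine tumour 5, -0.54, lay below the -0.50 of saline tumour 5, so the groups overlapped (exact permutation p = 0.0159, adjusted 0.0287). With M44 vaccine tumours 1 and 2 left out 14 of 21 members rose, at a median of 1.16. The antiviral genes Oas1a, Oas3 and Oasl2 rose by 1.41, 2.97 and 2.60, and Oasl1 went from 0.959 ± 0.217 to 6.26 ± 4.24 CPM.

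Myeloid markers rose. Of the macrophage list 10 of 13 genes passed the test (11 adjusted over the list alone; camera adjusted p = 3.45e-06; adjusted p = 0.336 with an estimated correlation). Cd68, a lysosomal protein of macrophages, went from 10.8 ± 2.11 to 37.6 ± 12.5 CPM, the complement genes C1qb and C1qc rose by 3.58 and 3.57, and the Fc receptor gene Fcgr1 by 3.15. In the monocyte list 5 of 9 genes rose (7 adjusted over the list alone; camera adjusted p = 0.000267; adjusted p = 0.336 with an estimated correlation), with Fcgr4, Itgam and Ccr2 at 4.22, 3.93 and 3.21. Itgam was at 3.18 without M44 vaccine tumour 1. In the dendritic cell list 9 of 13 rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 7.60e-05; adjusted p = 0.336 with an estimated correlation). Itgax, Wdfy4 and Flt3 rose by 2.96, 2.68 and 2.47, and Xcr1, a chemokine receptor of cross-presenting dendritic cells, by 4.16, or by 5.03 without saline tumour 2. In M44 vaccine tumour 5 the means of the 3 lists were -0.04, -0.35 and -0.23, against -1.06 ± 0.74, -1.15 ± 0.30 and -0.84 ± 0.10 in saline tumours (SD, n = 5). Without M44 vaccine tumours 1 and 2, 10 macrophage, 5 monocyte and 8 dendritic cell genes rose.

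Of the neutrophil list only 4 members were measured, and 2 rose, 2 adjusted over the list alone (camera adjusted p = 0.0335; adjusted p = 0.336 with an estimated correlation). These were Acod1, by 4.40, an enzyme that activated macrophages also make, and Clec4d, by 1.91, a lectin receptor also found on monocytes. S100a8, an abundant neutrophil protein, had 79 reads in all saline and 23 in all M44 vaccine tumours and was not tested. The list mean overlapped between the groups (exact permutation p = 0.0238, adjusted 0.0393). Without M44 vaccine tumours 1 and 2 the list did not pass camera (adjusted p = 0.158), nor did it without M44 vaccine tumour 1 alone (adjusted p = 0.0615). With a filter of 1 CPM in 5 libraries it did not pass either (adjusted p = 0.133). Without M44 vaccine tumour 2 the log2 fold changes of Acod1 and Clec4d were 3.69 and 1.26. The Clec4d call was lost without any 1 of the 5 saline tumours (adjusted p up to 0.0697).

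Genes of complement, chemokines and Toll-like receptor 9 signalling, the pathway that senses CpG, rose too. In complement 12 of 13 members rose (12 adjusted over the list alone; camera adjusted p = 5.01e-07; adjusted p = 0.336 with an estimated correlation), including C3ar1 by 2.74 and C3 by 2.51; C1qa, C1qb and C1qc are also in the macrophage list. Of the chemokines 12 of 16 rose (13 adjusted over the list alone; camera adjusted p = 1.07e-05; adjusted p = 0.336 with an estimated correlation), with Cxcl16, Ccl8 and Cxcl12 at 2.94, 2.95 and 2.28. Of the Toll-like receptor 9 list 9 of 14 rose (11 adjusted over the list alone; camera adjusted p = 0.000599; adjusted p = 0.336 with an estimated correlation). Tlr9 itself went from 0.327 ± 0.144 to 2.57 ± 1.94 CPM, and Irf5 and Unc93b1 rose by 3.46 and 1.89. Tlr2, which the list holds although it is another receptor than Toll-like receptor 9, rose by 1.89. The chemokine mean was 1.95 and 2.00 in M44 vaccine tumours 1 and 2 and 0.41, 0.56 and -0.38 in tumours 3, 4 and 5, against -0.91 ± 0.27 in saline tumours. Without M44 vaccine tumours 1 and 2, 11 complement, 9 chemokine and 9 Toll-like receptor 9 genes rose.

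Genes of immune checkpoints and of both kinds of macrophage activation rose in part. In the checkpoint list 5 of 6 members rose (6 adjusted over the list alone; camera adjusted p = 0.00113; adjusted p = 0.336 with an estimated correlation). Cd274, the PD-L1 gene, went from 7.79 ± 2.50 to 26.7 ± 16.3 CPM (log2 fold change 1.78, SE 0.42), and Entpd1, Lag3 and Cd244a rose by 1.47, 2.69 and 2.16. The Cd274 call was lost without saline tumour 3 (adjusted p = 0.0515) and that of Cd244a without saline tumour 5 (0.0539). Of the inflammatory macrophage list 6 of 11 rose (6 adjusted over the list alone; camera adjusted p = 0.00657; adjusted p = 0.405 with an estimated correlation). The costimulatory genes Cd40 and Cd86 rose by 3.42 and 2.86, and Nos2, the inducible nitric oxide synthase, by 2.44, from 2.47 ± 1.17 to 13.5 ± 15.3 CPM. Of the alternative list 5 of 9 rose (7 adjusted over the list alone; camera adjusted p = 0.00657; adjusted p = 0.336 with an estimated correlation). Tgfb1 rose by 1.04 and the lectin genes Clec10a and Mgl2 by 4.25 and 3.04. Retnla had a log2 fold change of 6.02, from 0.179 ± 0.109 to 11.8 ± 19.6 CPM. Its call was lost with sample quality weights (1.74, adjusted p = 0.181) and on unfiltered log2(TPM + 1), and it did not pass the filter without M44 vaccine tumour 1, 2 or 3 or without tumours 1 and 2 together. For Arg1, the arginase gene, the log2 fold change was 2.13, from 2.18 ± 1.12 to 9.52 ± 7.24 CPM. The alternative list mean was 2.65 and 1.32 in M44 vaccine tumours 1 and 2 and between -0.05 and 0.17 in the other 3. Without those 2 tumours the inflammatory list did not pass camera (adjusted p = 0.162), and 3 inflammatory and 3 alternative genes rose. Nos2 and Arg1 then had log2 fold changes of 1.20 and 1.05 (adjusted p = 0.0675 and 0.171). With all tumours and a filter of 1 CPM in 5 libraries, the inflammatory list did not pass camera either (adjusted p = 0.0779). Without M44 vaccine tumour 1 the log2 fold changes of Clec10a and Mgl2 were 2.31 and 1.67, and that of Nos2 was 1.46 without tumour 2. Single tumours ended further calls. For Nos2 it was any 1 of the saline tumours, for Clec10a and Mgl2 saline 2, 3, 4 or 5, and for Arg1 saline 1, 3, 4 or 5 or M44 vaccine 1 or 2 (adjusted p up to 0.0670, 0.0597, 0.0631 and 0.0761).

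**Figure D2:**
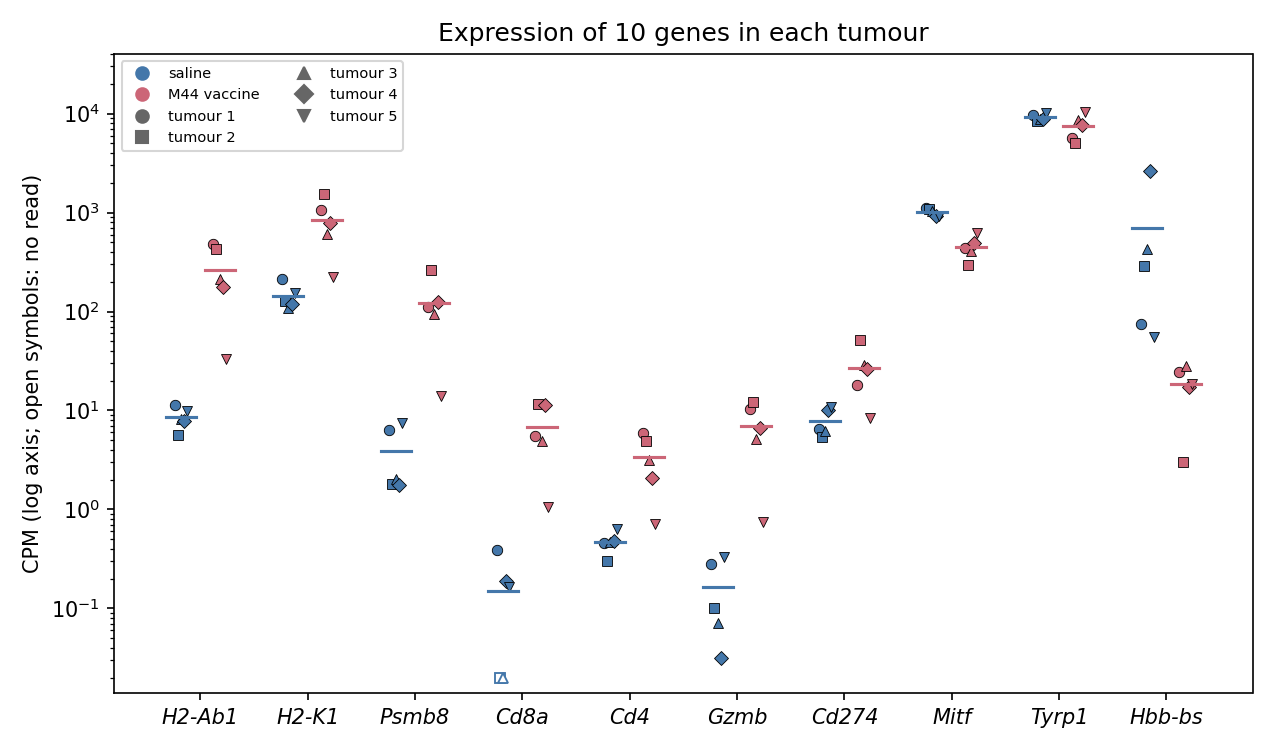
CPM of 10 genes in each tumour on a log axis (blue, saline; red, M44 vaccine; shape, tumour number; lines, mean of 5 tumours; open symbols at the bottom, no read). H2-Ab1 is higher in every M44 vaccine tumour than in any saline tumour, Mitf is lower, and Tyrp1 overlaps between the groups.

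Among the genes that fell at a mean log2 CPM of at least 0, the 5 with the largest change were erythroid genes. The globin genes Hbb-bs, Hbb-bt, Hba-a1 and Hba-a2 and Alas2, an enzyme of heme synthesis in erythroid cells, had log2 fold changes of -5.26, -5.17, -4.98, -4.82 and -5.51 (SE 1.12 to 1.18, adjusted p = 0.0120 to 0.0207). Without saline tumour 4 these were -3.53, -3.43, -3.16, -3.18 and -3.85. The 4 globin genes are 2 pairs of near-identical copies that may share reads. All 5 measured genes of the erythroid list fell, 5 adjusted over the list alone (camera adjusted p = 0.00297; adjusted p = 0.336 with an estimated correlation). The spread between saline tumours was wide: Hbb-bs stood at 700.4 ± 1105 CPM in saline and 18.3 ± 9.59 CPM in M44 vaccine tumours (SD, n = 5). The list mean was 0.06, 2.22, 2.66, 5.32 and -0.48 in saline tumours 1 to 5 and -1.96 ± 0.99 in M44 vaccine tumours (exact permutation p = 0.00794, adjusted 0.0177). Saline tumour 4, the highest, also held 53 of the 79 saline reads of S100a8. Without M44 vaccine tumours 1 and 2 none of these 5 genes passed (adjusted p = 0.0781 to 0.107), at log2 fold changes of -5.05 to -4.82. DESeq2 called 5 of the list's genes lower, and voom with sample quality weights 0.

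The other 7 of the 12 genes with the largest fall at a mean log2 CPM of at least 0, left after predicted genes were set aside, follow. Tenm4, a transmembrane protein of the teneurin family, had a log2 fold change of -2.15 (SE 0.57), from 14.9 ± 5.50 to 3.36 ± 3.16 CPM, and one of -2.85 without M44 vaccine tumour 5. Depp1 had -2.09 (SE 0.41, adjusted p = 0.00981), Clvs1 -1.86, Rgs4, a regulator of G protein signalling, -1.62, and the transporter gene Abca8a -1.58. Hapln1, which links hyaluronan and proteoglycans, had -1.56, from 29.3 ± 7.96 to 9.96 ± 7.46 CPM, and Slc16a7, a monocarboxylate transporter, -1.55. Depp1 kept its call without each single tumour. The others lost it without some, with adjusted p up to 0.0584 for Tenm4 (without saline 2, 3, 4 or 5), 0.0619 for Clvs1 (saline 1, 2, 4 or 5 or M44 vaccine 1) and 0.0663 for Rgs4 (saline 2, 3 or 4 or M44 vaccine 2). For Abca8a it was up to 0.0611 (saline 3, 4 or 5), for Hapln1 0.0839 (any saline tumour or M44 vaccine 1, 2 or 4) and for Slc16a7 0.0691 (saline 1, 3, 4 or 5 or M44 vaccine 1 or 2).

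In the melanocyte lineage 2 of 13 genes fell and 11 did not pass the test (2 fell adjusted over the list alone), and the list did not pass camera (adjusted p = 0.204). The genes called were not the same in every fit. DESeq2 called 1 higher and 2 lower, and voom with sample quality weights 2 and 3. With M44 vaccine tumours 1 and 2 left out, 4 were higher and 2 lower, and the median went from -0.11 to 0.09. Mitf went from 1017 ± 87.8 to 450.5 ± 117 CPM (log2 fold change -1.17, SE 0.17, adjusted p = 0.00498), lower in 5 of 5 M44 vaccine tumours than in any saline tumour. The pigment enzyme gene Dct went from 8090.3 ± 376 to 5939 ± 1160.1 CPM (-0.45, SE 0.13); its call was lost without any 1 saline tumour or M44 vaccine tumour 1 or 2 (adjusted p up to 0.0797). Tyrp1, another pigment enzyme gene, stood at 9208 ± 712 and 7466 ± 2164 CPM (adjusted p = 0.217). The list mean was -0.48 and -0.45 in M44 vaccine tumours 1 and 2 and 0.05, 0.12 and 0.17 in tumours 3, 4 and 5, against 0.12 ± 0.05 in saline tumours. Ints11, a subunit of the Integrator complex, stood at 31.0 ± 1.71 and 30.5 ± 5.01 CPM (log2 fold change -0.02, adjusted p = 0.889).

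Of the proliferation list 4 of 20 genes fell, and 0 adjusted over the list alone, where 8 had an unadjusted edgeR p below 0.05 and DESeq2 and voom with sample quality weights called 7 and 7 lower (camera adjusted p = 0.0335; adjusted p = 0.558 with an estimated correlation). Its median log2 fold change was -0.18. The mitotic genes Cenpf, Bub1, Kif11 and Ccnb1 had log2 fold changes of -0.91, -0.63, -0.76 and -0.39, with Cenpf at 146 ± 6.69 and 77.5 ± 32.2 CPM. Each of these 4 calls was lost without any 1 of the saline tumours (adjusted p up to 0.0991), and some without M44 vaccine tumours 1, 2 or 4. The list mean was -0.49 and -0.54 in M44 vaccine tumours 1 and 2 and 0.00, -0.07 and 0.19 in tumours 3 to 5, against 0.18 ± 0.04 in saline tumours. Camera gave an adjusted p of 0.143 without those 2 tumours and of 0.130 without tumour 2 alone, and without those 2 tumours 1 gene was higher and 6 lower.

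Genes of mitochondrial respiration rose. Of the mitochondrially encoded genes 12 of 13 passed the test, 12 adjusted over the list alone, with a median log2 fold change of 0.99 (camera adjusted p = 7.60e-05; adjusted p = 0.336 with an estimated correlation). mt-Nd1 and mt-Nd4 rose by 0.99 and 0.61, and mt-Co2 and mt-Co3 by 2.01 and 2.19, with calls lost without saline 3 for mt-Co2 (adjusted p = 0.0527) and without saline 3, 4 or 5 for mt-Co3 (up to 0.0533). Both were also lost on unfiltered log2(TPM + 1), with adjusted p of 0.0663 and 0.0726. The list mean was 1.10 and 1.24 in M44 vaccine tumours 1 and 2 and 0.29, -0.06 and -0.05 in tumours 3 to 5, against -0.50 ± 0.28 in saline tumours. Without tumours 1 and 2, 6 of the genes rose. Of the nuclear-encoded oxidative phosphorylation genes 7 of 19 rose, 12 adjusted over the list alone, with a median of 0.36 (camera adjusted p = 0.000609; adjusted p = 0.336 with an estimated correlation). Uqcrc1, Ndufv1 and Cox5a rose by 0.46, 0.36 and 0.59. The Uqcrc1 call was lost in 4 of 23 settings, none of them with a single tumour left out. Across settings its log2 fold change went down to 0.068 and its adjusted p up to 0.660. The Cox5a call was lost without any 1 saline tumour or M44 vaccine tumour 2 (adjusted p up to 0.0646). After removal of trends with gene length and GC content, the log2 fold change of Ndufv1 was -0.050 (limma adjusted p = 0.660). On log2(TPM + 1) the list's median was 0.07 where that of all genes was -0.26. The cytosolic ribosomal protein list passed camera (adjusted p = 0.0182; adjusted p = 0.668 with an estimated correlation) although 0 of its 23 genes passed the edgeR test, and 0 adjusted over the list alone. At an unadjusted p below 0.05 there were 13, and DESeq2 called 5 higher and 1 lower, and voom with sample quality weights 0 and 2. Rplp1 had a log2 fold change of 0.77 (adjusted p = 0.0607), and passed without M44 vaccine tumour 3 or 5 (adjusted p = 0.0353 and 0.0286). Its camera call was lost without saline tumour 3 (adjusted p = 0.0545) and without M44 vaccine tumour 1 (adjusted p = 0.0959), and its adjusted p was 0.739 once trends with length and GC content were removed.

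Fibroblast genes rose, and no endothelial gene passed the test with all tumours. Of the fibroblast list 7 of 12 genes rose, 10 adjusted over the list alone (camera adjusted p = 0.00344, and 0.484 with an estimated correlation). Fry did not call the list (adjusted p = 0.0865). Pdgfra, a receptor of fibroblasts, rose by 1.71, the matrix proteoglycan gene Dcn by 2.65, and the collagen gene Col1a2 by 1.40, and Col1a1 went from 167 ± 41.8 to 473 ± 342 CPM. The list mean was 2.20 and 1.58 in M44 vaccine tumours 1 and 2 and 0.25, -0.45 and -0.12 in tumours 3 to 5, against -0.69 ± 0.67 in saline tumours (exact permutation p = 0.0397, adjusted 0.0580). Without tumours 1 and 2, 1 of 12 fibroblast genes rose, and voom with sample quality weights, which count those 2 tumours least, called 1. Without single tumours the 4 named calls were lost, each without saline 2, 3, 4 or 5, the collagens also without saline 1, and all but Pdgfra without M44 vaccine 1 or 2 (adjusted p up to 0.0869). In the matrix list 5 of 17 rose and 1 fell, 6 and 1 adjusted over the list alone. Camera gave an adjusted p of 0.0862, and of 0.535 with an estimated correlation. It was 0.0164 without M44 vaccine tumour 4, 0.00602 on log2(TPM + 1) and 0.0372 after trends with gene length and GC content were removed. Tgfbi, Itga5 and Tnc rose by 2.94, 0.36 and 1.70, and the transcription factor gene Zeb2 fell, with a log2 fold change of -0.70. Without tumours 1 and 2 of the M44 vaccine group 2 matrix genes rose and 1 fell. The Itga5 and Tnc calls were lost without saline 2, 3, 4 or 5 or M44 vaccine 2, and that of Tnc also without saline 1 or M44 vaccine 1 (adjusted p up to 0.0678 and 0.0661). No gene of the endothelial list (12 measured) or of the pericyte and smooth muscle list (8 measured) passed the edgeR test over all genes or over the list alone. At an unadjusted p below 0.05 there were 0 and 1, DESeq2 called 0 and 0, and voom with sample quality weights called 0 endothelial genes and 1 pericyte gene higher and 1 lower (camera adjusted p = 0.214 and 0.388). In the fit without M44 vaccine tumours 1 and 2, 1 endothelial and 1 pericyte gene were higher and 0 of either list lower, with medians of 0.06 and -0.07 against -0.18 and -0.45. Emcn and Erg of the endothelial list had log2 fold changes of -0.50 and -0.60, and Rgs5 and Cnn1 of the pericyte list -1.09 and 0.99 (edgeR adjusted p = 0.136, 0.240, 0.113 and 0.102).

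Markers of skeletal muscle varied within both groups. The skeletal muscle list mean was 1.80 in saline tumour 3 and 3.19, 2.57 and 1.85 in M44 vaccine tumours 3 to 5, and -3.07, -3.38 and -2.72 in saline tumour 5 and M44 vaccine tumours 1 and 2, and none of its 10 genes passed the edgeR test, with 0 at an unadjusted p below 0.05 and 0 called by DESeq2, while voom with sample quality weights called 3 higher (Mb and Tnnt3 adjusted p = 0.122 and 0.199, with log2 fold changes of 2.50 and 1.88, and 3.14 and 2.72 without saline tumour 3). Camera gave an adjusted p of 0.592 for the list, and of 0.00106, with 3 genes higher in the vaccine group, once M44 vaccine tumours 1 and 2 were left out. The keratinocyte gene Krt5, picked after its values were seen, had 366 reads in M44 vaccine tumour 2 and 92 in tumour 3, and 1 in all saline tumours. Sbsn, the only keratinocyte gene with enough reads for the test, stood at 3.13 ± 0.723 and 3.33 ± 2.06 CPM (log2 fold change 0.09, adjusted p = 0.863). It was called lower by voom with sample quality weights and without M44 vaccine tumours 1 and 2 (-0.69, adjusted p = 0.0369). Of the adipocyte list 1 of 4 genes rose (1 adjusted over the list alone), Lipe, a lipase also used outside fat, by 0.86, and the list did not pass camera (adjusted p = 0.209) except without M44 vaccine tumour 2 (adjusted p = 0.0490).

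B cell genes did not pass the edgeR test. Of 5 measured members 2 had an unadjusted p below 0.05, DESeq2 called 0, voom with sample quality weights called 2 higher, and the list did not pass camera (adjusted p = 0.209). Cd79b had a log2 fold change of 1.82 (adjusted p = 0.0956), passing without saline tumour 4 (3.03, adjusted p = 0.0328) or M44 vaccine tumour 5 (2.10, adjusted p = 0.0433), and Cd22 did not pass either (adjusted p = 0.104), and its log2 fold change was 0.78 to 1.90 when 1 tumour was left out. The immunoglobulin constant genes of the plasma cell list, Igha, Ighm and Igkc, rose by 2.80, 2.62 and 2.14 (3 of 3 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.0569). It did so without any 1 saline tumour (adjusted p = 0.0162 to 0.0394) and without M44 vaccine tumour 1 (adjusted p = 0.000243). It also did without M44 vaccine tumours 1 and 2 (0.00130), on log2(TPM + 1) (0.00275) and after trends with gene length and GC content were removed (0.0219). With an estimated correlation it did not pass camera (adjusted p = 0.336). The plasma cell list passed fry (adjusted p = 0.00699) and the exact permutation test on list means (adjusted p = 0.0287). Reads of such genes may be shared between copies. The log2 fold change of Ighm was 3.50 without saline tumour 4 and 1.84 without M44 vaccine tumour 1. The Ighm call was lost without saline 1, 2, 3 or 5 or M44 vaccine 1, and that of Igkc without any saline tumour or M44 vaccine 2, 3 or 4 (adjusted p up to 0.0763 and 0.0886).

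The remaining lists did not pass camera with all tumours. Of the p53 response 4 of 13 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.348). Fas, Pmaip1 and Phlda3, which act in cell death, rose by 2.09, 2.49 and 1.02, and Zmat3 fell, with a log2 fold change of -0.50. The first 3 calls were lost without saline 2, 4 or 5, and those of Pmaip1 and Phlda3 also without saline 1 or 3 or M44 vaccine 1 or 2 (adjusted p up to 0.0750). In hypoxia and glycolysis 2 of 18 rose (0 adjusted over the list alone, 4 with an unadjusted p below 0.05, 3 by DESeq2; camera adjusted p = 0.160, and 0.0266 and 0.0421 without M44 vaccine tumours 3 and 4), Pfkfb3 by 0.31 and Aldoa by 0.64. Voom with sample quality weights called 2 of its genes higher and 5 lower. Without M44 vaccine tumours 1 and 2 it was 2 and 4, at a median of -0.11 against 0.35 with all tumours. In angiogenesis 1 of 12 rose (0 adjusted over the list alone, 2 with an unadjusted p below 0.05, 1 by DESeq2; camera adjusted p = 0.204), Pgf, a growth factor of the VEGF family, by 0.94, while the list's median was -0.36. Voom with sample quality weights called 0 angiogenesis genes higher and 4 lower, and the fit without M44 vaccine tumours 1 and 2 0 and 2. The calls of Pfkfb3, Aldoa and Pgf were lost without any 1 saline tumour or M44 vaccine 2, and those of Aldoa and Pgf also without M44 vaccine 1 (adjusted p up to 0.0928). In the unfolded protein and integrated stress response 1 of 13 fell (1 adjusted over the list alone; camera adjusted p = 0.962), Asns, asparagine synthetase, with a log2 fold change of -0.29; its call was lost without saline 5 (adjusted p = 0.0508). Voom with sample quality weights called 1 of these genes higher and 3 lower, as did the fit without M44 vaccine tumours 1 and 2 (1 and 3). The weights count those 2 tumours least, so the fits are not separate checks. None of 3 mast cell genes and none of 16 immediate early and heat shock genes passed the edgeR test over all genes or over the list alone. At an unadjusted p below 0.05 there were 0 and 1, DESeq2 called 0 and 0, and voom with sample quality weights 0 and 1, the latter lower (camera adjusted p = 0.646 and 0.798). Of the latter list 2 genes were lower without M44 vaccine tumours 1 and 2. Their members with the smallest p were Mcpt4 and Hdc, at log2 fold changes of 0.91 and 0.35, and Nr4a1 and Hspa1b, at -0.53 and -1.23 (adjusted p = 0.0842 and 0.177). Single tumours moved these values: Mcpt4 was at 1.49 without saline tumour 1, and Hdc at 1.28 without saline tumour 4 and -0.14 without M44 vaccine tumour 2. Hspa1b was at -0.15 without saline tumour 4. Nr4a1 passed without M44 vaccine tumour 1 (-0.73, adjusted p = 0.0202). No eosinophil or lymph node stroma gene had enough reads for the test.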

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

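The removal of trends with gene length and GC content, the test of a lower share of melanoma cells, the fit without M44 vaccine tumours 1 and 2, the ratio of B to T cell reads and the fit without saline tumour 4 were chosen only after the results they address were seen.

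In the M44 vaccine group, tumour 5 lay far below the other 4 for 8 named genes. On the log2 CPM scale, its gap to the nearest tumour over the whole range of the group was 0.753 for H2-Aa, 0.757 for Cd74, 0.739 for Slamf8 and 0.745 for Fcgr1. It was 0.829 for Fcgr4, 0.838 for Wdfy4, 0.728 for Xcr1 and 0.738 for Serpina3g, against Dixon's critical value of 0.71. H2-Aa stood at 5.09 in tumour 5 and between 7.92 and 8.84 in the others. For single genes, Igkc was far lower in M44 vaccine tumour 1 than in the rest of its group, at a ratio of 0.960, and higher in saline tumour 4, at 0.754. Serpinb2 was higher in saline tumour 2 (0.795), Clvs1 and Foxp3 were lower in saline tumour 3 (0.721 and 0.843), and Hbb-bs was lower in M44 vaccine tumour 2 (0.784). These are 14 of 356 groups examined, 3.93%, where chance gives about 1 in 20.

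For the numbers of genes, chance is argued against by 100 drawn splits of the 10 tumours into 5 and 5, the real one included. They cannot tell the treatment from another difference that follows the groups. Only 1 split, the real one, gave as many as 2400 genes higher, and only 1, the real one, as many as 1610 lower. The highest of the other splits gave 0 and 0. For the numbers of gene lists by camera, none of which passed with an estimated correlation, chance is not excluded. As many as 21 lists higher came from 22 of the 100 splits, with up to 25, and as many as 2 lower from 75, with up to 8. Every split but the real one held 3 or 4 of the 5 M44 vaccine tumours on 1 side. Their counts are thus not free of a difference between the groups, and the number of lists cannot decide. List by list, the exact permutation test on list means called 23 of 38.

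M44 vaccine tumours 1 and 2 stood apart from the other 8 tumours on the first principal component. A trend with gene length and GC content as the whole cause is argued against, because 87.7% of their squared distance from the others was left after its removal. A lower share of melanoma cells that raises every other cell type alike is argued against too. The gap between the fibroblast and endothelial list means lay at least 4.92 saline SDs above the saline mean in each of the 2 tumours. What stays open is a stronger response in these mice, another place of sampling within the tumour, a change in fibroblasts themselves and any difference in handling, none of which was tested.

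Leukocyte and antigen presentation lists were higher in M44 vaccine tumours. Of the 9 that passed camera, 8 also passed without M44 vaccine tumours 1 and 2, and only the neutrophil list was lost. All 9 passed after trends with gene length and GC content were removed. With an estimated correlation none of the 9 passed with all tumours (adjusted p = 0.336), so these camera calls cannot decide about either cause. Without the 2 tumours, 14 of 15 T cell, 9 of 10 class II and 15 of 17 class I genes still rose by edgeR. So did 5 of 9 monocyte and 2 of 4 neutrophil genes. For these genes the 2 tumours are not the whole cause. The named class I and class II genes, among them H2-Ab1, Cd74, H2-K1 and B2m, kept their call in all 23 settings. The removal of trends with length and GC content was 1 of these. They were mostly named for a small p, so for the lists as a set such a trend stays open. Lymph node tissue as the source is argued against for the M44 vaccine tumours summed. B cell reads (Ms4a1, Cd79a, Fcer2a and Cr2) came to 0.0779 of T cell reads there, against 2.22 in saline. M44 vaccine tumours 1 and 2 held 752 and 1506 of the 3324 T cell reads, and Cd79a made up 216 of the 259 B cell reads. In M44 vaccine tumour 5 there were 43 B and 75 T cell reads, so for that tumour the sum cannot decide. An effect of the peptide, an effect of CpG, which no group received alone, and other differences between the mice stay open.

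Erythroid genes were lower in M44 vaccine tumours. Saline tumour 4 alone is not the whole cause, because without it the 5 measured erythroid genes still fell by edgeR (adjusted p = 0.0220 to 0.0426). The list also passed camera without that tumour (adjusted p = 0.00113). With all tumours it did not pass with an estimated correlation (adjusted p = 0.336). Without that tumour the log2 fold change of Hbb-bs was -3.53, against -5.26 with it. Blood in saline tumour 4 may add to the difference: of the neutrophil granule and platelet genes with enough reads, all 11 had their highest CPM of the 10 tumours there. The other saline tumours, of which 1 and 5 lay closest to the vaccine group, leave bleeding, blood left in the vessels and red cell formation open for the rest.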

How the results depend on the processing

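The fits without M44 vaccine tumours 1 and 2 and after removal of trends with gene length and GC content were chosen after seeing the data. Against 2400 genes higher and 1610 lower, RLE gave 2435 and 1593, upper-quartile scaling 2647 and 1552, DESeq2 3545 and 2329, and a filter of 1 CPM 2207 and 1542. Voom with sample quality weights gave 2831 genes lower, and no filter beyond 1 read 754. Limma on log2(TPM + 1) gave 791 higher and 2958 lower, on log2(TPM + 0.1) 770 and 2580, and on unfiltered log2(TPM + 1) 422 and 413. The TPM fits changed the tool and the filter besides the scale. On log2(TPM + 1) the median of all genes moved by -0.26, and the causes of these changes were not tested. Limma on log2 CPM gave 2019 higher and 1825 lower, and 996 and 1719 once trends with length and GC content were removed. A minimum absolute log2 fold change of 1 left 1007 and 195. With 1 tumour left out, the range was 1011 to 3479 genes higher, 382 to 2555 lower, and 1 to 2 lists lower, and the cause was not tested. The estimated correlation gave 0 lists higher and 0 lower. A filter of 1 CPM gave 16 higher and 2 lower of the 31 lists that could then be tested. Fry gave 1 list lower, as did the fit without M44 vaccine tumours 1 and 2. Fry did not call the fibroblast, proliferation and cytosolic ribosomal protein lists (adjusted p = 0.0865, 0.116 and 0.258). Serpinb2 reversed to -1.49 and Sbsn to -0.68 with voom weights, Sbsn to -0.69 without M44 vaccine tumours 1 and 2, and Ndufv1 to -0.050 after removal of the length and GC trends; the cause was not tested. Of 118 named genes called, 56 kept direction and call in every setting that measured them, 20 to 23, and 62 lost the call in at least 1. With the replicate number as a block, 1628 genes were higher, 1338 lower, and 21 lists higher and 2 lower. Tumours of 1 number did not pair, with correlations of -0.04 to 0.18 and 2 of 5 closest to their own number. Depth limits genes such as Ifng, which had 5 reads in all saline tumours.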

Other observations

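The genes named in this part were chosen after their values were seen. Further constant-region genes of immunoglobulin rose in M44 vaccine tumours. Reads of B cell and plasma cell genes, many too few for the test, went both ways. Ighg2c, the constant region of an antibody class, went from 0.309 ± 0.194 to 3.14 ± 2.67 CPM (SD, n = 5; log2 fold change 3.32, edgeR adjusted p = 0.0317), above the saline range in 4 of 5 tumours. Ighg2b had a log2 fold change of 2.67 (adjusted p = 0.0466). Ms4a1 had 34 reads in all saline tumours and 3 in all M44 vaccine tumours, and Ighd 64 and 12. Of these, 26 and 45 were in saline tumour 4. Cd79b had 40 and 156 reads, Cd22 74 and 261, and the plasma cell genes Mzb1, Derl3 and Jchain 33 and 27, 28 and 58, and 23 and 255. Jchain had a log2 fold change of 3.11 with no filter beyond 1 read (edgeR adjusted p = 0.0330) and 3.13 by DESeq2 (adjusted p = 0.00101). The other 6 of these B cell and plasma cell genes did not pass in either of those 2 fits. Fcer2a, another B cell gene, had 28 reads in all saline and 3 in all M44 vaccine tumours. DESeq2 called it lower (log2 fold change -3.41, adjusted p = 0.0284), and edgeR with no filter beyond 1 read did not (adjusted p = 0.0560). An exact permutation test on CPM called neither Jchain nor Fcer2a (adjusted p = 0.156 and 0.0648). Fcer2a had the smallest p that this test can give before adjustment, so for it the test cannot decide. Immunoglobulin genes have near-identical copies, and whether these share reads was not tested.

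M44 vaccine tumour 1 held 664 reads of Ighm, the heavy chain of IgM, beside 5 of Igkc, the kappa light chain. The other M44 vaccine tumours held 290, 268, 142 and 58 reads of Ighm and 226, 200, 154 and 158 of Igkc. The Klra genes Klra7 and Klra8, below the filter, had 2 and 0 reads in all saline and 81 and 32 in all M44 vaccine tumours. Their family has near-identical copies, so these values are uncertain.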
